A study of Mus musculus with 9 samples.

How the data were processed

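MicroRNA (miRNA) abundance was measured in primary visual cortex of C57BL6 mice at postnatal day 28. Per the labels, 3 samples came from mice reared under a normal light cycle (control), 3 from mice kept in darkness from birth (dark-reared) and 3 from mice with 1 eye closed by lid suture from postnatal day 24. In the last group (monocularly deprived), the cortex opposite the closed eye was taken. Per the labels, 100 ng of RNA was labelled with Cy3 and hybridised to Agilent mouse miRNA arrays at 64 °C, 1 array per sample. Nothing in the labels says that the replicates were separate animals or pools, so the p-values measure only the spread between these samples, which may be technical.

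The deposited files hold fluorescence intensity values for 13715 spots per array, of which 13000 belong to miRNA probes and 715 to controls. Per the file headers, Agilent Feature Extraction 10.1.1.1 subtracted the background and removed a spatial trend, and the authors applied no scaling between arrays in these files. The authors' series matrix was compared with the processed intensity in the scanner files, and 100% of spots were equal within a relative difference of 1e-05. The arrays hold 1857 probes for 611 mouse and 39 viral miRNA names. Feature Extraction called 297 to 359 of the 611 mouse names detected per array, and the number of arrays limits the precision of each value. A total of 367 to 638 of the 13000 miRNA spots per array were called outliers by that program and left out. Saturation was called at 3 spots over all arrays, 0 of them a spot of a tested miRNA in use.

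The processed intensity was averaged over the spots of a probe and then, on the linear scale, over the probes of a miRNA. It was divided by the 75th percentile of each array, taken over the 433 probes well above background on all 9 arrays, which was 401 to 1022 intensity units. Scaled values under the 1st percentile of the detected miRNAs (0.00422, log2 -7.89) were raised to it, and log2 was taken. A mouse miRNA was tested where it was called detected on all 3 arrays of at least 1 group, which left 318. The linear model of limma 3.58.1 in R 4.3.3 was fitted to all 9 arrays with 3 group means, 6 residual degrees of freedom and default empirical Bayes moderation (2.21 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 was called a change. Where no array of 1 group held a probe well above background for a miRNA, the fold is a lower bound ("at least"). For it, the dim group was set at its own value or, where higher, at the lowest miRNA signal well above background on each array. Where its own value was used, the bound equals the fold between the group means. This holds for miR-483, miR-574-3p, miR-468, miR-505, miR-467a and miR-378*. No bound allows for the spread between arrays.

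A total of 21 lists of miRNAs (activity-regulated, genomic clusters, seed families and cell type markers) were written down beforehand, and 19 had at least 3 tested members. Each was tested with camera in limma at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it, and no list passed with an estimated correlation in any of the 3 comparisons. Members past the threshold were also counted after adjustment over the list alone. The rule for named miRNAs took up to 12 of largest change per direction past the threshold, filled to 20 by p-value. For the comparison of the 2 deprivations it took up to 6 per direction, filled to 8. It added miR-132, miR-212, miR-124, miR-9, miR-29a and let-7c to each comparison, and up to 4 members of smallest p from each list. Examples are printed for the lists that passed and for the activity-regulated list alone, a choice made after the data were seen. The samples, tests, lists, naming rule and the alternatives not described as added were fixed before the data were examined.

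The array headers place the control and dark-reared arrays on slide 1 and scan 1, and the 3 monocularly deprived arrays alone on slide 2 and scan 2. Slide and group therefore cannot be told apart in either comparison with the monocularly deprived arrays, and a slide block could not be fitted there. Same-numbered control and dark-reared arrays deviated together from their group means (r = 0.887, 0.324 and 0.815 across miRNAs, which are not independent replicates), so those numbers pair the arrays, which also share a column of slide 1, although control replicate 2 correlated more with dark-reared replicate 3 (r = 0.615) than with its own number. With the replicate block, 1 miRNA was called between dark-reared and control. No pair of arrays of 1 group differed by as little as the spot noise, with squared differences at least 3.29 times that noise, and all were kept as separate samples.

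The alternatives changed the scaling, background correction (normexp in limma, offset 50), summary of probes, filter, floor, test, block and source of values, and left out each array in turn. A block on slide 1 alone, a fit without control replicate 1 and dark-reared replicate 1, and 3 further normexp runs were added after the data were seen. The pipeline was tested on simulated data made from the 318 miRNAs, with 20 changed miRNAs of each size in 20 runs. For dark-reared minus control, 63.2%, 86.8% and 97.2% of changes of 0.5, 1 and 2 log2 units were recovered, with 4.63% of calls false. For monocularly deprived minus control these were 58.2%, 88.2% and 95.2%, with 3.97% false. For dark-reared minus monocularly deprived they were 62.8%, 87.2% and 96.2%, with 3.90% false. The 3 sizes were changed in the same runs, so many miRNAs changed at once, which eases the adjusted threshold. The simulated noise was independent between miRNAs and between arrays, unlike that of the paired control and dark-reared arrays. These shares are therefore likely too high for a comparison with few changes, and few calls there do not show that little changed. Of the 318 tested names, 311 matched a hairpin gene in the mouse gene table of GRCm38.p6, which was used for names alone. Coordinates are not used here, because the files name no genome build.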

Results

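Mature miRNAs were profiled on 9 arrays, with 3 samples each of control, dark-reared and monocularly deprived primary visual cortex at postnatal day 28. Dark rearing removes vision through both eyes from birth, and 4 days of lid suture removes patterned vision through 1 eye late in development. The comparisons address which cortical miRNAs differ after each kind of visual deprivation. The arrays detected 310 to 333 mouse miRNAs in the control samples, 305 to 359 in the dark-reared and 297 to 317 in the monocularly deprived samples. Within groups, log2 signals correlated at r = 0.972 to 0.999 across miRNAs. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD with n = 3 arrays per group.

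After dark rearing, miR-132 fell and miR-200b rose. miR-132, which is transcribed with miR-212 from 1 locus and is induced by neuronal activity, dropped 2.25-fold from 2.33 ± 0.08 in control to 1.16 ± 0.12 in dark-reared cortex (log2 change -1.17, SE 0.17, limma adjusted p = 0.0365). miR-200b, of a family abundant in epithelia, was 1.69-fold higher, at -4.51 ± 0.06 against -5.26 ± 0.15 (log2 change 0.76, SE 0.12, adjusted p = 0.045). For each of them, all 3 dark-reared arrays lay outside the range of the 3 control arrays. Neither call was firm: miR-200b lost its call with the replicate block, and both were lost with the block on slide 1 alone. The partner miR-212 had a log2 change of -0.45 (adjusted p = 0.174) and did not pass.

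The other miRNAs of smallest p-value did not pass. Above control in the dark-reared samples were miR-429 (log2 change 0.66, adjusted p = 0.0682) and miR-7b (0.52, adjusted p = 0.0682), followed by miR-676 (0.40), miR-204 (0.46), miR-7a (0.53), miR-551b (0.37), miR-200a (0.50), miR-101b (0.21) and let-7a* (0.54), with adjusted p of 0.24 to 0.412. The let-7a* probes carry the name of 1 other miRNA, so its value is uncertain. Below control were miR-667 (-0.40), miR-135b (-0.59), miR-126-5p (-0.25), miR-1902 (-0.53), miR-674 (-0.48), miR-222 (-0.285), miR-690 (-0.43) and miR-22* (-0.20), with adjusted p of 0.204 to 0.468. The abundant neuronal miR-124 (log2 change 0.02, adjusted p = 0.942), the neuronal miR-9 (-0.13, 0.614), the glial miR-29a (-0.01, 0.96) and let-7c (0.08, 0.842) did not pass, and the signs for miR-124 and let-7c turned negative with scaling on all miRNA probes (-0.11 and -0.04) and without scaling (-0.21 and -0.14), following the median of all miRNAs (0.05, -0.08 and -0.175 in these 3 scalings), relative to which miR-124 stayed at -0.03 and let-7c at 0.04.

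**Figure D1:**
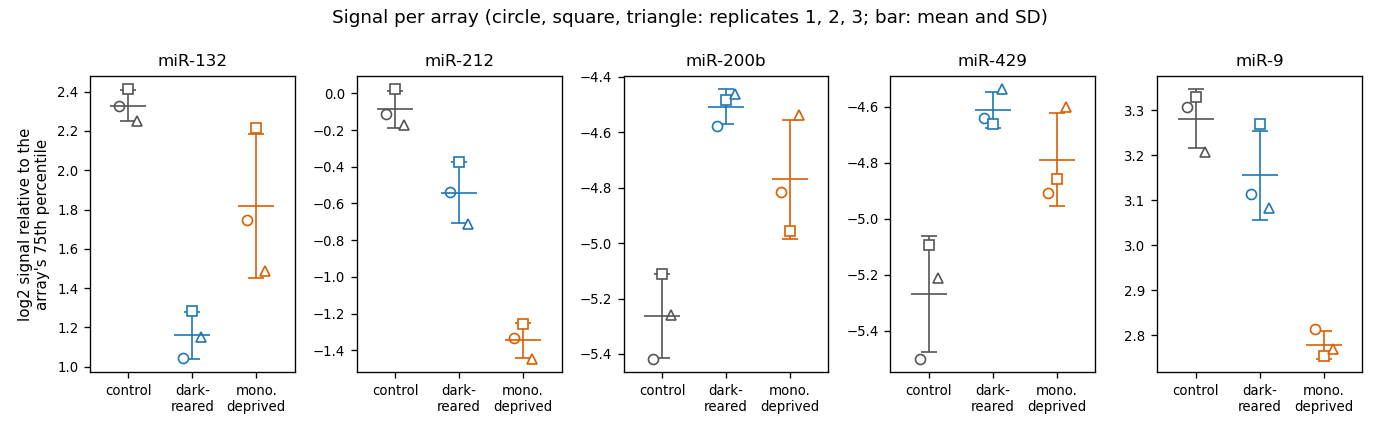
Log2 signal relative to the 75th percentile of the array (vertical axis) of miR-132, miR-212, miR-200b, miR-429 and miR-9 in the 3 groups, with 1 symbol per array (circle, square and triangle for replicates 1, 2 and 3) and bars for mean and SD. miR-132 is lowest in the dark-reared samples (1.16 ± 0.12) and miR-212 in the monocularly deprived samples (-1.34 ± 0.10). The fall of miR-132 and miR-9 after monocular deprivation turns to 0.04 and 0.05 with scaling on all miRNA probes, which is -0.58 and -0.57 relative to the median of all miRNAs.

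Of the 19 lists tested, 6 were shifted by dark rearing. The choroid plexus and epithelial list was shifted up (adjusted p = 4.6e-05, but adjusted p = 0.368 with an estimated correlation). It had 4 tested members, miR-200b, miR-429, miR-204 and miR-200a, all above control under each scaling, with a median log2 change of 0.58. Of the 4, miR-200b alone passed over all miRNAs and 4 passed when adjusted over the list alone. The activity-regulated list was shifted down (adjusted p = 0.0341, adjusted p = 0.376 with an estimated correlation). Of its 9 tested members 1 passed, miR-132, and 2 passed when adjusted over the list alone, miR-132 and miR-212, which come from 1 locus. The other members did not pass and lay on both sides of control. miR-146a (log2 change -0.19), miR-188-5p (-0.20), miR-381 (-0.11) and miR-329 (-0.01) were below it, and miR-134 (0.19), miR-485 (0.09) and miR-485* (0.78) above. The falls that passed therefore concern 1 locus and not the list as a class.

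The imprinted Dlk1-Dio3 list, a large cluster of neuronal miRNAs, was shifted down (adjusted p = 0.0206, adjusted p = 0.792 with an estimated correlation). The size was small: the median of its 52 tested members was -0.02 (-0.06 to -0.07 less than the median of all miRNAs under each scaling), 33 lay below 0, and 0 passed in limma, also when adjusted over the list alone. Its examples miR-667, miR-494 (-1.24, SE 0.56), miR-541 (-0.17) and miR-770-3p (-0.70) did not pass. The miR-23, miR-27 and miR-24 list was shifted down (adjusted p = 0.0464, adjusted p = 0.792 with an estimated correlation), with all 7 tested members below 0, among them miR-24-2* (-0.23), miR-27a (-0.18), miR-24 (-0.12) and miR-23a (-0.12), and 0 of the 7 passed, also when adjusted over the list alone. The vascular list was shifted down with the same p (adjusted p = 0.542 with an estimated correlation). It consists of miR-126-5p, miR-126-3p (-0.13), miR-145 (-0.10) and miR-143 (-0.04), of which 0 passed over all miRNAs and 1 passed adjusted over the list alone, miR-126-5p.

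The Sfmbt2 list, a cluster of repeat-derived miRNAs, was shifted up (adjusted p = 0.0464, adjusted p = 0.792 with an estimated correlation). Of its 17 tested members 16 lay above 0, with a median of 0.53, and 0 passed, also when adjusted over the list alone, among them miR-466a-3p (0.40, on probes that carry 4 other names), miR-467e (0.18), miR-669f (0.34) and miR-466h (1.14, SE 0.89). For the 14 members whose probes hold a CA or GT dinucleotide repeat, the median was raised on 3 arrays, although miR-466a-3p was not raised on control replicate 1 (-0.22 against the other control arrays). Relative to the mean of control replicates 2 and 3, it was 1.83 on control replicate 1, 2.21 on dark-reared replicate 1 and 1.26 on dark-reared replicate 2, against 0.08 on dark-reared replicate 3. The upward shift of the list therefore rests on 2 raised dark-reared arrays against 1 raised control array. Lists that did not pass included the neuronal (adjusted p = 0.541, 17 tested), astrocyte (0.541, 7 tested), oligodendrocyte (0.904, 3 tested), microglial and leukocyte (0.541, 5 tested) and erythrocyte lists (0.541, 3 tested), in none of which a member passed over all miRNAs (adjusted over the list alone, 1 neuronal member and 0 of the others did). Of the lists past the threshold none differed in sign between median, mean and test, whereas the oligodendrocyte, microglial, muscle and miR-34 lists did.

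In all, 2 of 318 miRNAs changed after dark rearing, 1 in each direction, against 28 with an unadjusted p under 0.05, where 15.9 would be expected by chance. In 59 miRNAs the groups did not overlap, where chance gives 10% or 31.8. Both calls were close to the threshold. With the replicate block miR-132 kept its call (adjusted p = 0.0271) and miR-200b did not (0.0543), and with the block on slide 1 alone neither did (0.0531 for each). Leaving out any 1 control or dark-reared array left 0 calls, with 20 to 39 unadjusted p under 0.05 in limma. Leaving out monocularly deprived replicate 1, outside this comparison, also ended both calls, because all groups share 1 estimate of the spread. The limma fit of the control and dark-reared arrays alone called miR-132 (adjusted p = 0.00564), miR-200b (0.0324) and miR-135b (0.0324). Among scalings, miR-132 lost its call without scaling alone (adjusted p = 0.44), and miR-200b with each other scaling (0.291 to 0.974). With a straight-line trend on probe GC content removed, a test chosen after the result was seen, miR-132 kept its call (0.0152) and miR-200b did not (0.145). That removal also centred each array anew, so a changed call cannot be assigned to GC content alone. With the replicate block the vascular list (adjusted p = 0.0718) and the miR-23 list (0.0512) were not shifted, nor was the activity-regulated list with the block on slide 1 (0.0849), with scaling on all miRNA probes (0.0537) or without scaling (0.118). The vascular and miR-23 lists were not shifted under any of the 3 other scalings (adjusted p = 0.0734 to 0.397), nor the Dlk1-Dio3 list without scaling (0.0681). The epithelial and Sfmbt2 lists were shifted under each scaling, but the first was not with normexp (0.106), nor the second with the total gene signal of the files (0.147), the brightest probe (0.0564) or the control and dark-reared arrays alone (0.123).

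After monocular deprivation many miRNAs differed from control, with the sharpest drops among miRNAs of low signal. miR-483, which lies within the Igf2 gene, was at least 13.99-fold lower (log2 -3.41 ± 0.08 in control, adjusted p = 4.03e-06), and miR-295* at least 12.16-fold lower (-4.16 ± 0.15 in control, adjusted p = 2.46e-07). Neither was well above background on any monocularly deprived array. miR-295* lay at the floor (-7.887) on all 3 of them, as did miR-678, named below. That group therefore added no spread, and the p-value of miR-295* is likely too small. miR-125a-3p, well above background on all 9 arrays of the study, fell by 2.39 log2 units (SE 0.14), and the 1 of its 4 probes that was well above background throughout fell by 1.65. miR-1894-3p (log2 change -2.73, SE 0.13) and miR-338-5p (-2.70, SE 0.16) also fell, but they were well above background on only 1 and 2 of the 3 monocularly deprived arrays, so the sizes of their falls are uncertain. The largest rises were near 2-fold, in miR-34c (1.04, SE 0.32, adjusted p = 0.0402) and miR-34b-5p (0.94, SE 0.29, adjusted p = 0.0402), which are made from 1 transcript and whose values overlapped those of control.

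The activity-regulated miR-212 fell 2.39-fold, from -0.09 ± 0.10 to -1.34 ± 0.10 (log2 change -1.26, SE 0.11, adjusted p = 4.39e-05), and stayed below control under each scaling. miR-132 was called lower by a narrow margin (log2 change -0.51, SE 0.17, adjusted p = 0.0497), and its change was 0.04 with scaling on all miRNA probes, which is -0.58 relative to the median of all miRNAs. Of 26 alternatives, 8 kept this call, 17 lost it and 1 turned its sign. miR-9, a regulator of neuronal differentiation, fell 1.42-fold (-0.50, SE 0.08, adjusted p = 0.00223), and its change was 0.05 with scaling on all miRNA probes, which is -0.57 relative to the median of all miRNAs. Values that did not pass were -0.004 for miR-124 (0.55 with scaling on all miRNA probes, which is -0.07 relative to the median of all miRNAs), 0.13 for miR-29a (-0.13 with quantile normalization and -0.10 without scaling) and 0.34 for let-7c (adjusted p = 0.0668).

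Other miRNAs that fell, and were not well above background on any monocularly deprived array, were miR-574-3p (at least 6.58-fold lower), miR-125b* (at least 6.07-fold), miR-721 (at least 5.82-fold) and miR-678 (at least 5.71-fold). miR-466g (-2.78, SE 0.78), miR-466f-3p (-2.47, SE 0.65) and miR-1187 (-2.41, SE 0.53) also fell. On the monocularly deprived arrays miR-466g lay at -7.18, -5.83 and -7.12, close to miR-574-3p (-6.97, -5.78 and -7.13). The size of the miR-466g fall is therefore uncertain. Control values of miR-466g, miR-466f-3p, miR-1187 and miR-574-3p varied widely, with SDs of 0.92 to 1.31, because control replicate 1 lay 1.59 to 2.27 log2 units above the other control arrays. The bound of miR-574-3p therefore depends on that array, and its call was lost in 11 of 25 alternatives. Among miRNAs dim in control, miR-505 rose at least 1.74-fold, miR-467a at least 1.64-fold, miR-378* at least 1.58-fold and miR-186* at least 1.34-fold. miR-18a (0.81, SE 0.14), miR-7a (0.77, SE 0.17), miR-330 (0.65, SE 0.18), miR-28 (0.61, SE 0.17), the oligodendrocyte miR-219 (0.59, SE 0.18) and miR-99a (0.57, SE 0.10) rose as well, with adjusted p of 0.00341 to 0.0389. The size for miR-330 is uncertain, because it was well above background on only 1 of the 3 control arrays and the others lay at the floor. With the planned normexp correction miR-505, miR-467a, miR-378*, miR-186*, miR-18a, miR-330 and miR-28 turned to falls, as did miR-34c and miR-34b-5p. They did not once a few spots of very bright background were left out of that fit.

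The list of miR-17 to miR-92 cluster miRNAs and their paralogs, which promote proliferation in many tissues, was the 1 list of 19 that shifted after monocular deprivation (camera, adjusted p = 0.00778, adjusted p = 0.899 with an estimated correlation). Of its 10 tested members 9 rose, and adjusted over the list alone 9 were higher and 1 was lower. Examples are miR-18a, miR-20a (0.58, SE 0.11), miR-19b (0.50, SE 0.10) and miR-93 (0.38, SE 0.07), whose 2 probes differed in sign. The median change of the list was 0.40 to 0.41 above that of all miRNAs under each scaling, but the call was lost with scaling on all miRNA probes (adjusted p = 0.0951), quantile normalization (0.0553), no scaling (0.0736) or normexp (0.291). Of the 9 tested members of the activity-regulated list, 5 passed both over all miRNAs and adjusted over the list alone: miR-212, miR-132, miR-134 (-0.96, SE 0.20) and miR-188-5p (-0.76, SE 0.18) fell, and miR-329 rose (0.34, SE 0.11). The falls of miR-134 and miR-188-5p were not called under any of the 3 other scalings (adjusted p = 0.0502 to 0.827). The rise of miR-329 lost its call in 16 of 26 alternatives. That list as a whole did not pass by camera (adjusted p = 0.431), but by fry it passed as lower (adjusted p = 0.0177). The list of miR-17 to miR-92 paralogs also passed by fry, as higher (adjusted p = 0.0177). The median of the activity-regulated list was -0.51, or -0.59 relative to the median of all miRNAs. With scaling on all miRNA probes it was 0.04, or -0.58 relative to that median. With quantile normalization it was -0.01, only -0.14 relative to that median. For markers of other cells, 7 of 17 members of the neuronal list passed (4 higher, 3 lower) and 2 of 3 of the oligodendrocyte list (1 higher, 1 lower). So did 2 of 4 of the vascular list (both lower) and 2 of 4 of the epithelial list (both higher). Adjusted over the list alone, the counts were 8, 2, 2 and 3. The vascular 2 were miR-126-5p (-0.63) and miR-145 (-1.24), while miR-126-3p (0.18), from the hairpin of the first, and miR-143 (0.12) did not fall. In the oligodendrocyte list miR-338-5p fell, and miR-338-3p (0.19), from the same hairpin, did not. None of these lists was shifted by camera. By fry, the oligodendrocyte (adjusted p = 0.0299) and vascular lists (0.0257) passed as lower and the epithelial list (0.034) as higher.

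In all, 105 of 318 miRNAs changed, 50 higher and 55 lower, with 138 at an unadjusted p under 0.05. Of these calls 31 were lower and 1 was higher by over 2-fold. The groups did not overlap in 168 miRNAs, where chance gives 10% or 31.8. The number and the split depended on the processing: scaling on all miRNA probes gave 201 higher and 33 lower (median of all miRNAs 0.62, against 0.08), quantile normalization 66 and 36 (0.13), no scaling 0 and 36 (-0.16), and normexp background correction 2 calls, or 6 once a few spots of very bright background were left out. Because the deprived samples were alone on slide 2, where the bright corner control spots were also dimmer (log2 change -4.47, against -0.37 for dark-reared minus control on slide 1), slide and group cannot be told apart. A second control probe, dmr_3, differed far less. Its signal was 12204 ± 682 intensity units on slide 2, against 15229 ± 734 in control and 15758 ± 613 in dark-reared samples.

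The direct comparison tested whether the deprivations differed from each other. miR-132 was lower after dark rearing than after monocular deprivation (log2 change -0.66, SE 0.17, adjusted p = 0.0249), whereas miR-212 was higher (0.80, SE 0.11, adjusted p = 0.000879), so that the members of this pair ranked the deprivations in opposite orders. miR-9 was also higher after dark rearing (0.38, SE 0.08, adjusted p = 0.00956), although its difference was -0.30 with scaling on all miRNA probes, which is 0.40 relative to the median of all miRNAs. miR-124 (0.02, but -0.66 with scaling on all miRNA probes, which is 0.05 relative to the median of all miRNAs), miR-29a (-0.14, but 0.06 with quantile normalization) and let-7c (-0.25) did not pass. The difference of miR-212 shrank to 0.13 and lost its call with scaling on all miRNA probes (adjusted p = 0.547), where the median of all miRNAs lay at -0.70. Relative to that median the miR-212 difference was 0.83.

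The largest differences were in miRNAs close to or under the background in the monocularly deprived samples. miR-483 was at least 13.62-fold higher in the dark-reared samples, miR-295* at least 13.22-fold, miR-574-3p at least 11.7-fold and miR-468 at least 8.88-fold. miR-466g (3.56, SE 0.78) and miR-466f-3p (3.12, SE 0.65) were higher as well. These bounds concern the dim group alone and are not limits over the spread between arrays. For miR-483, miR-574-3p and miR-468 they equal the fold between the group means. The values of the 4 repeat-bearing miRNAs (miR-574-3p, miR-468, miR-466g and miR-466f-3p) were carried by dark-reared replicates 1 and 2. Without dark-reared replicate 1 their log2 differences were 2.89, 2.51, 2.93 and 2.58, and miR-468 lost its call (adjusted p = 0.135), while without dark-reared replicate 2 both miR-468 (0.1) and miR-574-3p (0.0509) did. Lower after dark rearing were miR-467a (-0.88, SE 0.17), miR-186* (-0.80, SE 0.21), miR-18a (-0.66, SE 0.14), miR-505 (-0.62, SE 0.17) and miR-219 (-0.59, SE 0.18), with adjusted p of 0.00743 to 0.0423. Of these, miR-219 alone was well above background on all dark-reared arrays, and the others on 1 of the 3, so the sizes of their differences are uncertain. The calls were lost in 14 of 26 alternatives for miR-219, 11 of 25 for miR-505 and 10 of 25 for miR-186*. For miR-467a and miR-18a these were 2 of 25 and 2 of 26. With the planned normexp correction miR-467a, miR-186*, miR-18a and miR-505 turned positive, but not once the spots of very bright background were left out.

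By camera, 2 lists were lower after dark rearing than after monocular deprivation. In the Dlk1-Dio3 list (adjusted p = 0.000732, adjusted p = 0.869 with an estimated correlation) 44 of 52 tested members lay below 0, 9 passed as lower and 3 as higher. Adjusted over the list alone, 5 were lower and 1 was higher. Its examples were miR-411 (-0.47, SE 0.08), miR-337-3p (-0.48, SE 0.10) and miR-409-3p (-0.32, SE 0.08), which were lower, and miR-134 (1.14, SE 0.20), which was higher. In the list of miR-17 to miR-92 paralogs (adjusted p = 0.00897, adjusted p = 0.869 with an estimated correlation) 5 of 10 tested members passed, all lower, and adjusted over the list alone 9 were lower and 1 was higher. Its call was lost with scaling on all miRNA probes (adjusted p = 0.196), quantile normalization (0.0692), no scaling (0.132) or normexp (0.4). Besides miR-18a these included miR-93 (-0.36, SE 0.07), miR-20a (-0.46, SE 0.11) and miR-20b (-0.38, SE 0.09). The activity-regulated list did not pass (adjusted p = 0.915), with 2 of 9 members higher and 2 lower (4 and 3 adjusted over the list alone), miR-329 being lower (-0.35, SE 0.11). The call of miR-329 was lost in 19 of 26 alternatives.

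In all, 91 miRNAs differed, 60 higher and 31 lower after dark rearing, with 137 at an unadjusted p under 0.05 and 148 without overlap of the groups, where chance gives 10% or 31.8. Scaling on all miRNA probes gave 247 calls, 35 of them higher (median of all miRNAs -0.70, against -0.03), quantile normalization 111, 36 of them higher (-0.12), and no scaling 37, all higher (-0.02), while normexp gave 1 call, or 3 without the spots of very bright background, and slide and group cannot be told apart here either.

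The 2 deprivations were then compared through their changes against the same 3 control arrays. Across the 318 miRNAs, which are not independent replicates, the changes correlated at r = -0.05 (Spearman rho 0.22), where simulated unchanged groups that shared these controls gave r = 0.50 ± 0.12 (SD of 1000 simulations). That simulation leaves out the pairing of control with dark-reared arrays (pooled r of the deviations 0.73), which lowers the expected value: with the pairing, added after the result was seen, it gave r = 0.26 ± 0.16. The covariance was -0.0112 against 0.036 without and 0.00997 with the pairing, differences of -0.0471 and -0.0211. The same sign was seen in 62.9% of miRNAs, against 66.7% and 58.3% in the simulations. Both simulations took 1 spread per miRNA pooled over the groups, and the second took 1 correlation for all miRNAs. Repeat-bearing miRNAs varied more among control and dark-reared arrays than among monocularly deprived arrays, so the simulated values are approximate. Called in both comparisons were miR-132, which fell, and miR-200b, which rose, against 0.17 and 0.16 miRNAs for independent lists. Neither overlap was firm. In limma, miR-200b lost its call after dark rearing with the replicate block (adjusted p = 0.0543) and under each other scaling. miR-132 lost its call after monocular deprivation in 17 of 26 alternatives and turned its sign in 1. The 3 control arrays could not be split into parts of at least 2, so part of any excess may come from the shared controls. The fall of miR-132 after monocular deprivation turned to 0.04 with scaling on all miRNA probes, which is -0.58 relative to the median of all miRNAs.

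**Figure D2:**
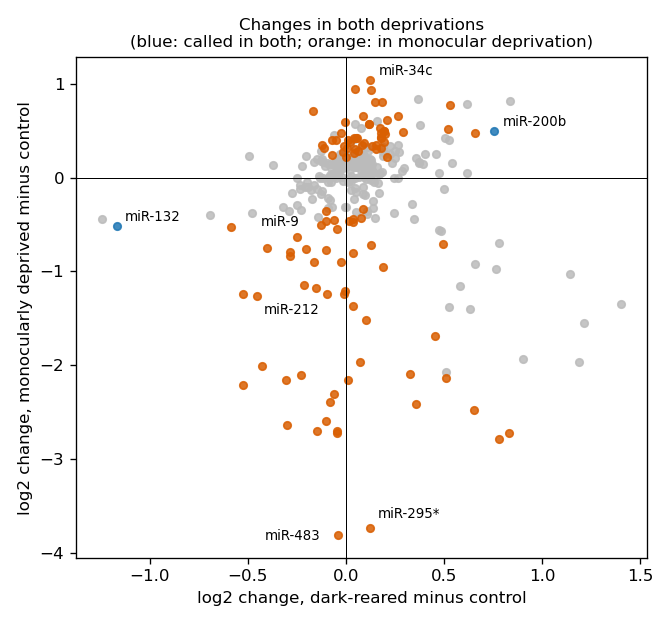
Log2 change of each of 318 miRNAs in dark-reared minus control (horizontal axis) against monocularly deprived minus control (vertical axis), 1 point per miRNA. Blue points were called in both comparisons (miR-132 and miR-200b), orange points after monocular deprivation alone and grey points in neither. Changes reach -3.81 on the vertical axis for miR-483. The changes of miR-132 (-0.51) and miR-9 (-0.50) on that axis turn to 0.04 and 0.05 with scaling on all miRNA probes, which is -0.58 and -0.57 relative to the median of all miRNAs.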

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

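The tests of slides, probe GC content, probe repeats, array column, epithelial tissue and other splits of the samples were chosen after the results were seen. The tests between dark-reared and monocularly deprived samples had been fixed before the data were examined.

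The direct test between dark-reared and monocularly deprived samples called 91 miRNAs, 1 to 247 among the alternatives, and it cannot tell a difference between the deprivations from one between slides. miR-132 differed by a log2 change of -0.66, and miR-212 by 0.80 in the other direction. The miR-212 difference shrank to 0.13 (0.83 relative to the median of all miRNAs) and lost its call with scaling on all miRNA probes. Outside the mouse miRNAs, 4 of 39 viral miRNA names were called detected on all 9 arrays (3 of mouse cytomegalovirus and 1 of a mouse gammaherpesvirus), with log2 signals in control of -4.32 ± 0.23, -1.58 ± 0.10, -1.70 ± 0.10 and -5.92 ± 0.32. The source of this signal was not tested, so a detection call alone does not show that the named RNA was present.

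Each comparison of 3 against 3 arrays allows 10 splits of the samples, too few for a share under 0.05. For dark-reared minus control the real split gave 2 calls, and 2 of the 10 splits gave at least as many, the highest other being 24. That split set the 3 arrays raised in repeat-bearing miRNAs (control replicate 1 and dark-reared replicates 1 and 2) against the remaining arrays, whereas the 3 other splits with both replicate 1 arrays on 1 side gave 0 calls by limma (10 to 26 unadjusted p under 0.05). The other 3 splits that part all same-numbered arrays, as the real one does, gave 0 calls by limma and 2 to 6 unadjusted p under 0.05, and the replicate block gave 1 call. For monocularly deprived minus control the real split gave 105 calls and the highest other 0 (0 to 14 unadjusted), so 1 of 10 splits was as large. For dark-reared minus monocularly deprived the real split gave 91 calls and the highest other 0 (1 to 30 unadjusted), again 1 of 10. In these 2 comparisons every other split mixes slides 1 and 2 on each side. A difference by slide or by deprivation would then widen the spread and lower the calls alike, so the splits cannot separate them.

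The 105 calls after monocular deprivation have a technical and a biological explanation. The tables argue against a straight-line trend with probe GC content as the whole cause, because removing it from every array left 162 calls, 91 of them shared with the 105. The removal also centred each array anew, which acts as a second scaling. Gained or lost calls therefore cannot be assigned to GC content alone. In dark-reared minus control that removal left miR-132 called (adjusted p = 0.0152) but not miR-200b (0.145), and it called miR-212 (0.0236) and miR-135b (0.0326). A difference between slides or scans stays open and cannot be told apart from the deprivation. The 6 viral names detected on all control arrays had a median change of -0.73 (range -2.64 to 0.56) on slide 2. For dark-reared minus control on slide 1 their median was -0.06. The source of the signal on these probes was not tested, so their change cannot be assigned to the slide alone. The loss of input from 1 eye is the biological difference named by the design, and it was not tested apart from the slide.

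A set of 20 miRNAs was over 1 log2 unit higher on control replicate 1 and on dark-reared replicate 1 than on the other arrays of their groups, and it was raised on dark-reared replicate 2 as well (median 1.96, 2.39 and 1.27 relative to control replicates 2 and 3, against 0.11 on dark-reared replicate 3). Hybridisation that follows the repeat in the probe is a candidate explanation for those with repeats: 8 repeat-bearing miRNAs outside the Sfmbt2 list were higher by a median of 1.18 (1.46 in control, 0.91 in dark-reared), as was the median of 14 inside it, whereas 3 members of that list without the repeat were at -0.15 and 293 others near 0 (-0.10 and -0.05). Of the 20, 6 hold no repeat, among them miR-207, miR-485* and miR-494, named here after their values were seen. Chosen in the same way, let-7b, miR-377 and, on control replicate 1, miR-466a-3p hold the repeat and were not raised (-0.20, -0.09 and -0.22 in control), so the repeat neither accounts for all raised miRNAs nor raised all that hold it. The column of the array on the slide stays open for the replicate 1 arrays, whose deviations correlated at r = 0.887, since on slide 1 the column and the replicate number cannot be told apart, but column 1 alone does not account for dark-reared replicate 2, which lay in column 2 with control replicate 2, an array that was not raised. No biological explanation was tested, because the labels name nothing shared by these samples.

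The higher value of miR-200b after dark rearing, the only 1 of the 4 tested members of its list to pass, may reflect choroid plexus or other epithelial tissue in the pieces. It lost its call with the replicate block (adjusted p = 0.0543) and under each other scaling, and its list did with an estimated correlation (0.368). Of the 7 list names not tested, 1 was detected on more dark-reared than control arrays and 6 on no array, in this test of epithelial tissue, which leaves this open because their levels in such tissue relative to the tested members are not used here. The 4 tested members also lay above control in the monocularly deprived samples on slide 2 (miR-200b 0.49, miR-429 0.48, miR-200a 0.43 and miR-204 0.25), where 2 passed. Each was therefore lowest in control, and the rise was not seen after dark rearing alone. A change within cortical cells after dark rearing is the other explanation, and it was not tested. The labels describe no sort that would remove such tissue.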

How the results depend on the processing

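The block on slide 1, the fit without the replicate 1 arrays of control and dark-reared and the normexp fits other than the planned one were chosen after the data were seen. Changes are log2 values, and the cause of each difference was not tested unless stated. For dark-reared minus control, the 2 calls became 1 with scaling on all miRNA probes, 1 with quantile normalization, 0 without scaling (3 at an unadjusted p under 0.05 in limma), 0 with normexp (2 unadjusted), 1 with the total gene signal of the files, 4 with detection on all 9 arrays, 1 with a lower floor, 5 with array quality weights (whose fit gave a convergence warning), 1 with the replicate block, 0 with the replicate block on slide 1 (55 unadjusted), 1 without the replicate 1 arrays (miR-466h, named after its value was seen) and 1 with normexp without spots of very bright background, and ranged from 0 to 3 leaving out 1 array. The repeat-bearing miR-466h lay at the floor (-7.887) on control replicates 2 and 3 and on all monocularly deprived arrays. Neither of those groups had spread in the fit without the replicate 1 arrays, so its call there is uncertain. Without the detection filter 2 were called, none of them among the original 2. For monocularly deprived minus control, the 105 calls became 234 with scaling on all miRNA probes, 36 without scaling, 2 with normexp, 61 without the replicate 1 arrays of control and dark-reared and 6 with normexp without bright background spots, and 66 to 104 leaving out 1 array. For dark-reared minus monocularly deprived, the 91 calls became 247, 37, 1 and 3 with scaling on all miRNA probes, no scaling, normexp and normexp without those spots, and 49 to 91 leaving out 1 array. Without the replicate 1 arrays of control and dark-reared, monocularly deprived minus control had 12 higher and 49 lower, against 50 and 55 as reported. Dark-reared minus monocularly deprived then had 56 higher and 7 lower, against 60 and 31. The planned normexp fit left a 5th percentile of 592 intensity units on control replicate 1 and 325 on dark-reared replicate 3, because 4 and 5 spots had a local background over 10 times the median of the array. An offset of 0 and maximum likelihood gave the same counts as planned, and the fit without those spots brought these percentiles to 13.2 and 11.05. Of the 6 lists shifted in dark-reared minus control, 0 held with an estimated correlation (2 unadjusted), 1 with fry, 3 with scaling on all miRNA probes, 2 without scaling, 2 with normexp, 3 with the replicate block on slide 1, 3 without the replicate 1 arrays and 1 to 6 leaving out 1 array. In monocularly deprived minus control the count of 1 list became 0 with an estimated correlation (0 unadjusted), 5 with fry, 0 with quantile normalization (3 unadjusted), 2 with normexp (2 other lists, let-7 and Sfmbt2, while the list of miR-17 to miR-92 paralogs lost its call), 2 with the brightest probe, 2 with the replicate block on slide 1 and 4 with normexp without bright background spots. With scaling on all miRNA probes or without scaling the count stayed at 1, but the list was Sfmbt2 in place of miR-17 to miR-92. In dark-reared minus monocularly deprived the count of 2 lists became 0 with an estimated correlation (0 unadjusted), 0 with fry (6 unadjusted), 1 with quantile normalization and 4 with normexp without those spots, and with scaling on all miRNA probes or without scaling it stayed at 2, with Sfmbt2 in place of the miR-17 to miR-92 list. The correlation of the 2 responses (-0.05) moved to 0.10 with detection on all 9 arrays and 0.27 with normexp without those spots, and ranged from -0.25 to 0.24 leaving out 1 array. Signs changed as follows. In dark-reared minus control, normexp without bright background spots gave 0.13 for miR-667, 0.047 for miR-126-5p, 0.10 for miR-1902, 0.10 for miR-674, 0.017 for miR-22*, -0.004 for miR-124, 0.054 for miR-146a, 0.061 for miR-143, 0.10 for miR-145 and 0.13 for miR-24-2*. No scaling gave -0.016 for miR-101b, -0.21 for miR-124, -0.14 for let-7c and -0.042 for miR-467e. The brightest probe gave -0.006 for let-7a* and 0.006 for miR-29a, scaling on all miRNA probes -0.11 for miR-124 and -0.043 for let-7c, quantile normalization 0 for miR-124, the total gene signal 0.029 for miR-29a and normexp -0.022 for miR-467e. Array weights gave -0.009 for miR-124, 0.009 for miR-29a, -0.006 for let-7c and 0.067 for miR-143. Leaving out 1 array, miR-124 ranged from -0.031 to 0.068, miR-29a from -0.049 to 0.027, let-7c from -0.025 to 0.20 and miR-143 from -0.19 to 0.079. In monocularly deprived minus control, normexp gave -0.28 for miR-34c, -0.21 for miR-34b-5p, -0.68 for miR-186*, -0.49 for miR-18a, -0.63 for miR-505, -0.575 for miR-467a, -0.60 for miR-378*, -0.69 for miR-330, -0.505 for miR-28, -0.088 for miR-93 and 0.12 for miR-124. Scaling on all miRNA probes gave 0.04 for miR-132, 0.55 for miR-124 and 0.049 for miR-9, quantile normalization 0.087 for miR-124 and -0.13 for miR-29a, no scaling -0.10 for miR-29a, the brightest probe 0.011 for miR-124 and the fit without the replicate 1 arrays 0.012 for miR-124. Normexp without bright background spots gave 0.076 for miR-134 and 0.014 for miR-188-5p, and leaving out 1 array moved miR-124 from -0.11 to 0.068. In dark-reared minus monocularly deprived, normexp gave 0.54 for miR-467a, 0.68 for miR-186*, 0.49 for miR-18a, 0.62 for miR-505, -0.10 for miR-124, 0.039 for miR-337-3p, 0.17 for miR-409-3p, 0.057 for miR-93 and 0.32 for miR-20b. Scaling on all miRNA probes gave -0.66 for miR-124 and -0.30 for miR-9, quantile normalization -0.087 for miR-124 and 0.063 for miR-29a, and leaving out 1 array moved miR-124 from -0.05 to 0.13. Same-numbered monocularly deprived arrays did not pair with control (r = -0.359, -0.259 and 0.213) or dark-reared arrays (-0.385, -0.274 and 0.137), and with the replicate block 104 and 87 calls were made in those comparisons, which ended the calls of miR-34b-5p (adjusted p = 0.0565), miR-219 (0.0601) and miR-329 (0.086) against control. With it the Sfmbt2 list passed between the deprivations (adjusted p = 0.0147), as in 12 of 22 alternatives for that list (0.0598 as reported), while miR-219 (0.0691) and miR-329 (0.0854) did not. It changed no other call of a named miRNA or list besides those given beside the results. In the 2 comparisons with slide 2, a slide block could not be fitted, and within slide 1 the fit of control and dark-reared arrays called 3 miRNAs. The values of the series matrix were those used and changed nothing. Over all alternatives, 2216 of 2639 values of named miRNAs kept their direction and their status as called or not called. Of the rest, 330 lost the call, 22 gained it and 71 changed sign. Many of the 2216 belong to miRNAs that had no call to lose. The dark-reared calls of miR-132 and miR-200b were kept in 15 and 9 of 27 alternatives. Of 1273 values of lists, 1168 kept their status, most of them because the list passed in neither fit. Another 73 lost the call, 32 gained it and 0 changed sign, the direction being compared only where at least 1 of the values passed. The 6 lists shifted by dark rearing kept their call in 5 (vascular) to 21 (epithelial) of 23 alternatives.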

Other observations

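The test of the ratio of miR-132 to miR-212 was chosen after the changes of both were seen.

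miR-132 and miR-212 come from 1 transcript, and the ratio of their signals within arrays restates the unequal changes that prompted it. Relative to miR-212, miR-132 changed by -0.72 log2 units in dark-reared minus control, by 0.74 in monocularly deprived minus control and by -1.46 in dark-reared minus monocularly deprived (SD of the ratio 0.14, 0.28 and 0.02 in dark-reared, monocularly deprived and control, n = 3 each). The exact permutation p was 0.1 (two-sided) in each, the smallest that 3 against 3 arrays allow, so this test cannot reach 0.05 and no difference is claimed from it. The ratio does not depend on a scaling that divides each array by 1 value, though it does on quantile normalization, and it does not show which of the pair changed. Both comparisons with the monocularly deprived arrays set slide 2 against slide 1.

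In the control and dark-reared samples, 2 of the 3 erythrocyte miRNAs were lowest on replicate 2. miR-451 was at 0.81, 0.31 and 1.26 in control replicates 1, 2 and 3, at 1.30, 0.42 and 1.12 in the dark-reared and at 1.36, 1.49 and 1.34 in the monocularly deprived samples. miR-144 was at -3.42, -4.26 and -3.12 in control, at -3.12, -4.28 and -3.17 in the dark-reared and at -3.17, -2.83 and -3.21 in the monocularly deprived samples. The other, miR-486, did not follow this order (-4.79, -4.70 and -4.34 in control, -4.52, -4.15 and -4.37 in the dark-reared samples), and in the monocularly deprived samples replicate 2 was the highest for each of the 3. These miRNAs were chosen after their values were seen.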
